A study of Homo sapiens with 12 samples.

How the data were processed

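RNA sequencing of polyA RNA was analysed from 2 human leukaemia cell lines, DAMI and SET-2, each infected with a control lentivirus or with a lentivirus that silences HMGA1 by a short hairpin RNA. Which hairpin was used, and whether another was tried, is not stated in the labels used here. Each of the 4 groups held 3 libraries, 12 in all. Groups and library numbers came from the sample titles. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

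Per the labels' protocols, DAMI was grown in RPMI medium with 10% serum and SET-2 with 20%, RNA was purified on columns after Trizol storage, and standard Illumina libraries were made. Per the submitters' processing notes, bcl2fastq 2.17, Bowtie2 2.2.1, TopHat, featureCounts of the Subread package and DESeq2 were used, with GRCh37/hg19 named as the build. The deposited values are raw counts per gene, whole numbers that sum to a different total in each library, so no normalization by the authors enters the values used here. The genome coordinates within the same files do not follow that build: of 56898 genes whose Ensembl identifier is in GENCODE release 29, 54784 (96.28%) have the start, end and strand that this GRCh38 annotation gives. Coordinates below are those of the files and are stated as GRCh38. Each file lists 57500 genes. Symbols were taken from GENCODE 29 by identifier, and 602 genes kept an identifier only. Whether the counting used strand is not given in the sources used here, so a gene and an antisense or overlapping partner cannot be separated, and genes with near-identical copies are named as uncertain.

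Total counts per library ran from 42801535 to 71498516. No pair of libraries agreed within sampling noise. The biological coefficient of variation was 37.9% in DAMI and 20.6% in SET-2, so the spread between libraries, not depth, set the precision of most genes. It was uneven within groups. Taken 2 libraries at a time, it was 11.0% for DAMI silenced 1 and 3, and 39.6% and 40.5% for silenced 2 with each. In SET-2 it was 11.2% for silenced 2 and 3, and 27.2% and 28.1% for silenced 1 with each. The SDs and p-values below take the 3 libraries of a group as independent, which the labels do not establish.

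Each line was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM normalization, a robust quasi-likelihood fit and a 2-sided quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from this test unless another tool is named. CPM values are edgeR's library-scaled counts (its cpm function) after TMM normalization. A fit of all 12 libraries gave the difference between the lines' responses. 23 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01, 2-sided), adjusted over the lists, then again with the correlation estimated from the data and with fry, which asks whether the genes of a list move one way without comparing them with other genes. The design, the lists, the rule for genes to be named and the alternatives were fixed before the data were examined, apart from the tests given below as chosen after. The naming rule was later extended to the average of both lines, to the DAMI result of the 12-library fit and to the DAMI calls with the date as a block. Genes named only from these were not fixed before. The lists hold pathways, blood lineages, markers of other cell types and signs of RNA quality, and the plot of gene lists shows the result of every list.

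Genes named were HMGA1, 8 fixed genes, and per line the 8 largest rises and 8 largest falls among genes past the threshold with an average log2 CPM of at least 1, a symbol of an ordinary gene, and all 3 silenced libraries on one side of all 3 controls. For each list past camera, or with 3 or more called members, up to 4 called members in the main direction and up to 2 in the other were named. For the difference between lines the 8 genes with the lowest p were named. 1 gene with an identifier only and 1 noncoding RNA with a clone name that this rule brought up in DAMI are counted but not described, and 2 genes it brought up in SET-2 are counted but not reported here.

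Alternatives were DESeq2 1.42.0, limma-voom, RLE normalization, no filter on low counts, a stricter filter (1 CPM in 3 libraries), all 12 libraries in one fit, the library number as a block, the label date as a block in DAMI, and each library left out in turn. The average response of both lines, the DAMI result of the 12-library fit as a result of its own, the test of SET-2 genes within DAMI, the test of gene lists on the difference between lines, the label month as a block and the removal of both February 2018 DAMI libraries were chosen after seeing the data.

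Whether library numbers pair the samples was checked from the correlation of each library's deviations from its group mean. In SET-2 the same-numbered control and silenced libraries correlated at 0.395, 0.290 and 0.468, so the numbers were read as pairs, from the data and not from the labels. In DAMI the labels carry dates. Control 1 and silenced 2 share 1 day in February 2018 and control 2 and silenced 3 share 1 day in May 2018, with correlations of 0.275 and 0.143, while silenced 1 is dated May 2018 and control 3 December 2016. The DAMI title numbers, with correlations of -0.295, -0.234 and 0.0956, do not mark pairs. Control 2 and silenced 1, both of May 2018 but of different days, correlated at 0.279, above both same-day pairs, so the correlations do not single out the day, and the label date was taken as the block from the labels. As a block it rests on 2 same-day pairs, since control 3 and silenced 1 are alone on their dates, which leaves 1 residual degree of freedom.

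The code was tested on simulated data drawn from the means and spreads of these libraries. At a simulated 4-fold change the edgeR test called 86.7% of changed genes in SET-2 (19969 genes tested) and 42.6% in DAMI (19906 tested). At 2-fold it called 56.6% and 2.02%. For the difference between lines it called 34% of genes simulated at 4-fold (22312 tested), and for the average of both lines 92% (22297 tested). In simulated DAMI libraries DESeq2 called 71% at 4-fold with 58 false calls among 20750 genes, against 1 for edgeR on the same 6 libraries. The edgeR fit of all 12 libraries made 47 false calls for DAMI, and found 11% of genes at 2-fold and 66% at 4-fold (100 of each). A list of 30 genes simulated 0.5 higher (log2) passed camera in DAMI and SET-2 (adjusted p = 1.26e-05 and 6.82e-14). With an estimated correlation it passed in SET-2 (adjusted p = 0.0197) and not in DAMI (0.108). Simulated genes were drawn independently, while the correlation estimated for the real megakaryocyte list was 0.275 in DAMI and 0.518 in SET-2, above the preset 0.01.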

Results

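The study silenced HMGA1, which encodes a high mobility group chromatin protein, in 2 cell lines and asked how gene expression changed. DAMI and SET-2 are human leukaemia lines, and the labels place both under myeloproliferative neoplasm and acute myeloid leukaemia. Each line was measured by RNA-seq in 3 libraries of cells with a control lentivirus and 3 of cells with the HMGA1 hairpin lentivirus. In DAMI the control libraries 1, 2 and 3 held 50035784, 70659998 and 66153548 counts in total and the silenced libraries 63296842, 60054709 and 46725840. In SET-2 the controls held 65211733, 62484990 and 42801535 and the silenced libraries 71498516, 56771592 and 61148431.

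HMGA1 (ENSG00000137309) lies on chromosome 6 from 34236873 to 34246231 in GRCh38, and the values below are sums over its annotated exons. In DAMI it stood at 1074 ± 156 CPM in control and 90.0 ± 44.7 CPM in silenced libraries (SD, n = 3), so 8.37% was left. In SET-2 it stood at 347 ± 19.4 CPM in control and 62.9 ± 40.4 CPM in silenced libraries (SD, n = 3), so 18.1% was left. The single silenced libraries kept 12.2%, 3.97% and 8.92% in DAMI and 31.56%, 10.998% and 11.81% in SET-2, libraries 1 to 3. All 3 silenced libraries lay below all 3 controls in both lines (exact 2-sided permutation p = 0.1, the smallest that 3 against 3 allow). HMGA1 fell in SET-2 (log2 fold change -2.46, SE 0.38, adjusted p = 0.0243), and in DAMI its log2 fold change of -3.58 (SE 0.43) had an adjusted p of 0.133. With the label date as a block, which rests on 2 same-day pairs, the DAMI value was -4.01, adjusted p = 0.0161, and with the label month as a block -3.83, adjusted p = 0.128. The SET-2 call of HMGA1 was lost without any 1 library other than silenced 1, with adjusted p 0.0920, 0.131 and 0.113 without controls 1, 2 and 3, and 0.109 and 0.0809 without silenced 2 and 3.

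**Figure D1:**
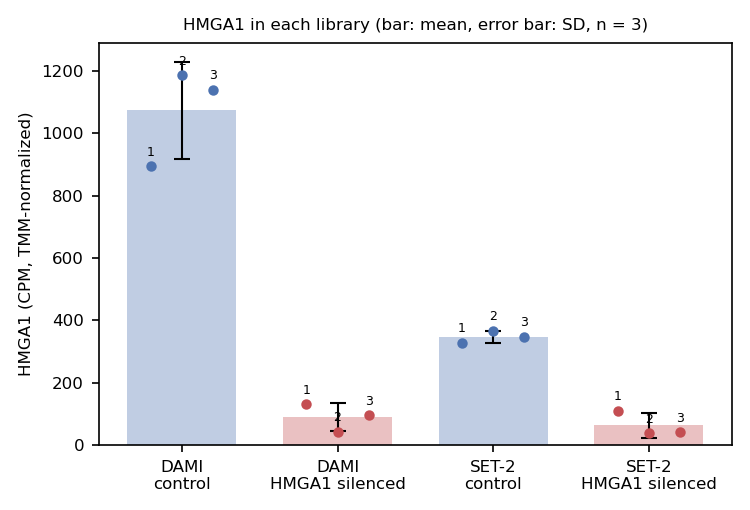
HMGA1 in CPM after TMM normalization for each library, with bars at the group mean and error bars of 1 SD (n = 3). Small numbers are library numbers. Silenced libraries lie between 42.7 and 131 CPM in DAMI and between 38.2 and 110 CPM in SET-2, below every control library of their line.

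In SET-2, silencing was followed by higher expression of 315 genes and lower expression of 272 of the 20381 tested. The largest rises among genes of the naming rule were in CXorf36, SLCO2B1, an organic anion transporter, CTSG, the granule protease cathepsin G, ADAM19, CLEC1B, which encodes the platelet receptor CLEC-2, DLGAP3, KCNMB1, a potassium channel subunit, and CXCL11, a chemokine. CXorf36 went from 0.341 ± 0.0105 to 5.96 ± 3.25 CPM (SD, n = 3; log2 fold change 4.11, SE 0.50, adjusted p = 0.0165). KCNMB1 went from 3.53 ± 0.0958 to 18.1 ± 3.59 CPM (log2 fold change 2.35, SE 0.18, adjusted p = 0.00677). Besides HMGA1, the largest falls included those of AFP, GPR153, ACPP, FAM84B, RHPN2 and BBS2, a gene of the ciliary BBSome. FAM84B went from 32.6 ± 6.32 to 8.98 ± 1.07 CPM (log2 fold change -1.86, SE 0.18, adjusted p = 0.0129) and GPR153 from 5.61 ± 1.08 to 1.32 ± 0.363 CPM (log2 fold change -2.09, SE 0.26, adjusted p = 0.0184). Of the rises 188, and of the falls 103, were at least 2-fold.

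At an unadjusted p under 0.05 there were 4513 genes in SET-2, where 1019 would be expected at random. With the library number as a block 1299 genes were higher and 1176 lower, and all 587 genes above were among them. The count rested on each library: of the 40 named genes 2, 0, 0, 1 and 4 stayed past the threshold without control 1, control 2, control 3, silenced 2 and silenced 3, and of the 587 calls 4, 0, 1, 2 and 8. Without silenced 1, whose HMGA1 was the highest of the 3 silenced libraries, all 587 stayed and 2518 genes were higher and 2479 lower. DESeq2 called 1148 and 897 genes, and the fit of all 12 libraries called 0 with edgeR (2208 at an unadjusted p under 0.05).

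**Figure D2:**
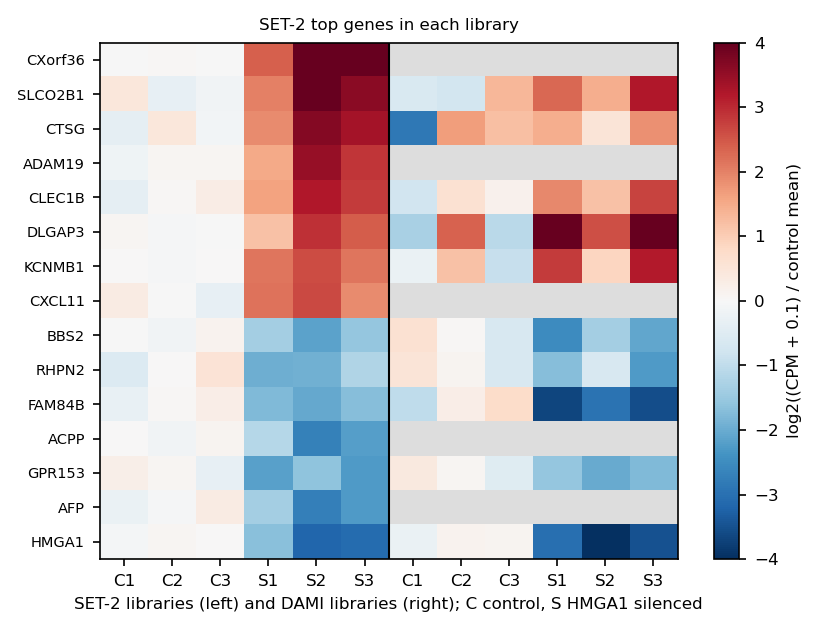
Log2 ratio of CPM (plus 0.1) to the geometric mean of the line's controls for the SET-2 genes named above, per library, with SET-2 on the left, DAMI on the right and genes not tested in DAMI in grey. In SET-2 silenced library 1 most of these genes moved less than in silenced libraries 2 and 3; HMGA1 kept 31.56% there against 10.998% and 11.81%.

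Megakaryocyte and platelet genes were higher in SET-2 after silencing in 32 of 34 tested members, with a median log2 fold change of 0.76. CLEC1B (0.806 ± 0.205 to 5.64 ± 2.82 CPM, SD, n = 3), GP5, a subunit of the platelet GPIb complex (6.60 ± 0.665 to 30.1 ± 14.6 CPM), and GP6, the platelet collagen receptor (20.7 ± 5.15 to 41.9 ± 8.42 CPM), rose. PF4, PPBP, ITGA2B and THBS1 moved little, with log2 fold changes of 0.20, 0.20, 0.21 and 0.16. ITGB3, GP9, GP1BA and VWF had 1.02, 1.32, 0.64 and 0.84. None of these last 2 groups of genes passed edgeR's test over all genes. 3 members passed over all genes and 14 adjusted over the list alone, all higher, and with the library number as a block 13 passed over all genes. The list passed camera (adjusted p = 1.61e-08) and did not with the correlation estimated (adjusted p = 0.671 with an estimated correlation). Without silenced 2 its median was 0.46 and without silenced 1 it was 1.06.

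All 13 mitochondrial transcripts, a sign of RNA quality as much as of expression, were higher in silenced SET-2 libraries, with a median log2 fold change of 0.56. MT-CO3 rose from 4675 ± 630 to 8884 ± 828 CPM (SD, n = 3), and MT-ND2, MT-ATP8 and MT-ATP6 also passed, 4 members over all genes, 10 adjusted over the list alone and 12 with the library number as a block. The mitochondrial share of counts was 4.14% to 5.54% in control and 6.63% to 7.40% in silenced libraries. The list passed camera (adjusted p = 2.08e-10), and its adjusted p was 0.671 with an estimated correlation. Nuclear copies of mitochondrial genes make these counts uncertain.

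In the interferon response list, 6 of 40 members rose and 0 fell over all genes, with 10 higher and 1 lower adjusted over the list alone. With the library number as a block 11 rose and 3 fell over all genes, and 15 and 9 adjusted over the list alone. IFIT2, IFIT1, RSAD2 and ISG20, antiviral genes that interferon induces, had log2 fold changes of 1.55, 1.35, 1.70 and 1.64, adjusted p 0.0123 to 0.0188. The other members went both ways, so the median was -0.01 and the mean 0.22, and the list passed camera as higher (adjusted p = 0.00671; 0.671 with an estimated correlation; 0.0571 without control 3, 0.612 without silenced 1 and 0.0865 with limma-voom). Among myeloid genes, CTSG, FCER1G and FPR1 were among those that rose and NCF1, whose near-identical pseudogenes make it uncertain, fell, with 8 higher and 2 lower adjusted over the list alone, of 24. Its camera adjusted p was 0.0158, 0.671 with an estimated correlation, 0.0716 without silenced 2 and 0.0928 with all 12 libraries in one fit. Of the heat shock and immediate early genes, a sign of handling stress, HSPA1A, HSPA1B and HSPB1 rose, 3 of 18 over all genes and 3 adjusted over the list alone. HSPA1A and HSPA1B are near-identical copies and uncertain one by one. That list's camera adjusted p was 0.00396, 0.671 with an estimated correlation, 0.128 without silenced 1 and 0.131 with all 12 libraries in one fit, and its median of 0.26 was 0.51, 0.10 and 0.06 without controls 1, 2 and 3 and 0.16 without silenced 2.

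Another 6 SET-2 lists passed camera, the cell cycle, cholesterol, erythroid and ribosomal ones with medians within 0.18 of 0. G2/M genes had a median of -0.18 with 0 of 50 members past edgeR's test over all genes or over the list alone; the block of library numbers called 1 higher and 8 lower. Cholesterol genes had a median of -0.18, and SC5D, a late enzyme of cholesterol synthesis, fell (1 of 32 over all genes, 2 adjusted over the list alone). Erythroid genes had a median of 0.16, and CA2, carbonic anhydrase, rose (1 of 41 over all genes and 1 adjusted over the list alone; 9 higher with the block). Ribosomal protein genes had a median of 0.14, and RPS25, which has processed copies in the genome, fell (1 of 82 over all genes, 0 adjusted over the list alone). Of the markers of other cell types, CD3D and CD79B (lymphoid, median 0.45, 3 higher and 1 lower of 13 adjusted over the list alone) and PDGFRB and THY1 (markers of fibroblasts, epithelium and endothelium, here called non-blood markers for short, median 0.46, 4 of 17 adjusted over the list alone) rose. PECAM1 of the non-blood list stood at 328 CPM in SET-2 controls and 266 CPM in DAMI controls. The lines themselves express it, so a rise of that list need not come from other cells. CD3D went from 0.0812 ± 0.0455 to 0.566 ± 0.163 CPM (SD, n = 3). The collagen gene COL1A1 was at 2.46 and 2.14 CPM, while COL1A2, COL3A1, DCN and LUM had log2 fold changes of 1.04, 1.13, 1.25 and 0.46. None of these passed edgeR's test over all genes. For each of these lists the adjusted p was 0.671 with an estimated correlation. Camera calls ended without control 1 (non-blood 0.223, ribosomal 0.111), control 2 (cholesterol 0.153), control 3 (erythroid 0.125, ribosomal 0.0662), silenced 1 (ribosomal 0.160), silenced 2 (erythroid 0.0765, lymphoid 0.0523, non-blood 0.0716) or silenced 3 (non-blood 0.130), and with limma-voom (non-blood 0.0557), the stricter filter (non-blood 0.0621) or all 12 libraries in one fit (lymphoid 0.0629, ribosomal 0.104). Medians also moved without control 1 (erythroid 0.30, lymphoid 0.22, cholesterol -0.27), silenced 1 (G2/M -0.28) and silenced 3 (erythroid 0.28, lymphoid 0.23). Among the called genes of the last 4 paragraphs, as among all 40 named, at most 4 stayed past the threshold when a SET-2 library other than silenced 1 was left out.

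**Figure D3:**
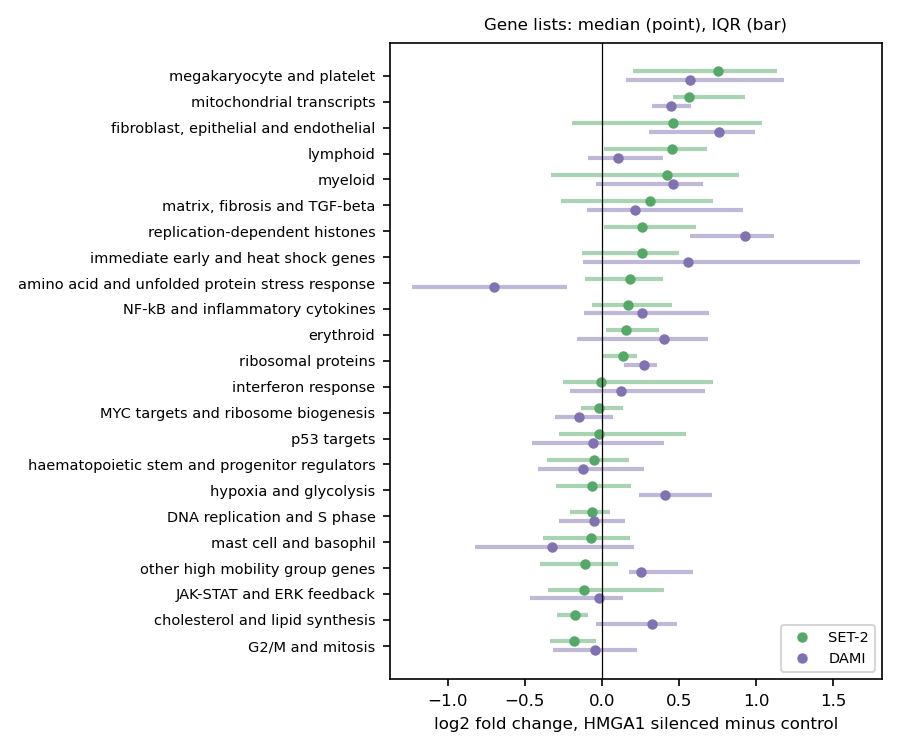
Median (point) and interquartile range (bar) of the log2 fold change, silenced minus control, over the tested members of each of the 23 gene lists, in SET-2 and DAMI. Megakaryocyte genes have medians of 0.76 in SET-2 and 0.57 in DAMI, and stress response genes 0.18 and -0.70.

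Of the 8 genes fixed for their part in blood cell growth, GATA2, a transcription factor of blood stem and progenitor cells, fell in SET-2 from 1169.9 ± 128 to 704 ± 106 CPM (SD, n = 3; log2 fold change -0.73, SE 0.15, adjusted p = 0.0427). In DAMI it went from 748 ± 64.0 to 294 ± 79.5 CPM, a log2 fold change of -1.35 (SE 0.25, adjusted p = 0.194). MYC had log2 fold changes of -0.56 in SET-2 (adjusted p = 0.167) and -1.44 in DAMI (adjusted p = 0.243). MYB had -0.49 in SET-2 (adjusted p = 0.0926; 0.0315 with the library number as a block) and -0.53 in DAMI. CDKN1A, the cell cycle inhibitor p21, had 0.94 in SET-2 (adjusted p = 0.136) and 1.25 in DAMI (adjusted p = 0.324). GATA1 (-0.02 and -0.05), KIT (-0.05 and 0.40), JAK2 (-0.26 and 0.62) and HMGA2 (-0.11 and 0.93) did not pass in SET-2 or DAMI. The SET-2 call of GATA2 ended without control 1, 2 or 3 (adjusted p = 0.129, 0.172 and 0.136) and without silenced 2 or 3 (0.194 and 0.128).

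In DAMI, no gene passed edgeR's test on the line's own 6 libraries (0 of 20750, lowest adjusted p = 0.133), with 2280 genes at an unadjusted p under 0.05 against 1037.5 expected. The label date as a block, which rests on 2 same-day pairs with 1 residual degree of freedom, called 5, and the label month 0 (3520 at an unadjusted p under 0.05): RD3, HLA-DPA1, an antigen presentation gene, CLU, the chaperone clusterin, and ITGAX, an integrin of myeloid cells, were higher and HMGA1 was lower. CLU went from 70.3 ± 16.4 to 447 ± 115 CPM (SD, n = 3), with a log2 fold change of 2.84 from the same-day pairs (adjusted p = 0.0426), and HLA-DPA1 from 24.5 ± 1.90 to 119 ± 54.9 CPM (2.49 from the same-day pairs, adjusted p = 0.0426). DESeq2 called 212 genes higher and 209 lower, and limma-voom and RLE normalization called 0. The first principal component (39.4% of the variance) set the February 2018 libraries, control 1 and silenced 2, apart from the other 4. Among those 4 it did not follow the date. Controls 2 and 3, of different dates, lay at 12.3 and 5.03, and silenced 3, of the same day as control 2, at 68.7. The second component (26.7%) parted the controls (13.2, 19.8 and 80.5) from the silenced libraries (-23.6, -52.6 and -37.3). Without both February 2018 libraries the count was still 0, with 5112 genes at an unadjusted p under 0.05.

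Replication-dependent histone genes, whose transcripts mostly lack a polyA tail, were higher in silenced DAMI libraries in 53 of 55 members (median log2 fold change 0.93). Genes of the amino acid and unfolded protein stress response were lower in 28 of 34 (median -0.70), and megakaryocyte genes were higher in 26 of 32 (median 0.57), as were non-blood markers in 14 of 16 (median 0.76). These 4 lists passed camera (adjusted p = 1.52e-11, 2.11e-05, 4.02e-05 and 0.00161) and kept the call without each library in turn, with 0.65 for each as the adjusted p with an estimated correlation. The medians moved, for megakaryocyte genes to 0.36 and 0.94 without controls 1 and 2, for stress genes to -0.35 without control 3 and for histone genes to 0.59 without silenced 2. 0 members passed edgeR's test over all genes; adjusted over the list alone, 1 stress gene was higher and 4 lower, 1 non-blood marker was higher, and 0 histone and 0 megakaryocyte genes passed. Without both February 2018 libraries the non-blood list's adjusted p by camera was 0.0588. Silenced 1 and 3 held a count for 39218 and 39390 genes, against 29978 to 34879 in the other DAMI libraries. Some non-blood markers lay near the floor, such as DCN at 0.141 CPM in control and 0.394 CPM in silenced libraries. Whether the excess of detected genes bears on their rise was not tested.

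Another 7 DAMI lists passed camera. Heat shock (median 0.56), myeloid (0.46), mitochondrial (0.45), hypoxia (0.41), erythroid (0.40) and ribosomal protein genes (0.27) were higher and MYC targets (-0.15) lower, with adjusted p 0.65 to 0.814 with an estimated correlation and 0 members past the test over all genes. Adjusted over the list alone, 1 heat shock gene was higher and 2 MYC targets were lower, with 0 in the other 5. In HSPA1B, silenced 2 held 1258 CPM against 125 and 84.1 CPM in silenced 1 and 3 and 21.2 to 55.5 CPM in the controls. With the label date as a block the mitochondrial and hypoxia lists did not pass (adjusted p = 0.147 and 0.222), nor hypoxia with the month (0.164). Without silenced 2 the medians were -0.28 (hypoxia), -0.12 (ribosomal), 0.02 (MYC targets), 0.12 (heat shock) and 0.09 (erythroid), and calls also ended without control 1 (myeloid 0.625), control 2 (erythroid 0.245, ribosomal 0.245, heat shock 0.0932), control 3 (erythroid 0.0664, hypoxia 0.433), silenced 1 (mitochondrial 0.169), silenced 2 (myeloid 0.0674) and silenced 3 (myeloid 0.120). Medians also moved without control 1 (hypoxia 0.83), silenced 1 (hypoxia 0.62, MYC targets -0.35) and silenced 3 (hypoxia 0.64, ribosomal 0.42). With no filter on low counts the erythroid (0.120), myeloid (0.145), hypoxia (0.1002) and ribosomal (0.426) calls ended, and without both February 2018 libraries those of the myeloid (0.465), heat shock (0.239), MYC target (0.955), hypoxia (0.864) and ribosomal (0.465) lists.

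Because no gene passed on the DAMI libraries alone, the DAMI contrast of the fit of all 12 libraries, whose spread is shared with SET-2, was chosen after that result was seen as a second account of the line. It called 138 genes higher and 158 lower of 23264; in simulated libraries this fit made 47 false calls beside 11 and 66 right ones at 2-fold and 4-fold, so single calls are uncertain. The largest rises among genes of the naming rule were in RD3, CCR4, a chemokine receptor, CHRNA2, WWC1, PRSS23, CD200R1, CLU and RAP1GAP. The largest falls besides HMGA1 were in FAM84B, SMARCA1, a chromatin remodelling ATPase, ADM2, COLGALT2 and DNASE2, a lysosomal nuclease. WWC1 (0.0307 to 0.892 CPM) and SMARCA1 (0.0415 to 0.844 CPM) lay near the floor in the DAMI libraries. They met the expression limit of the rule through SET-2. CHRNA2 went from 1.22 ± 0.525 to 14.2 ± 0.765 CPM (SD, n = 3; log2 fold change 3.50, SE 0.55, adjusted p = 0.0174) and FAM84B from 5.81 ± 3.09 to 0.416 ± 0.149 CPM (-3.83, SE 0.44, adjusted p = 0.00647). GATA2 and MYC passed as lower (adjusted p = 0.0174 and 0.0394). The counts depended on the libraries: 13 higher and 25 lower without control 3, 43 and 18 without silenced 1, 660 and 888 without silenced 2, and 9 and 4 without silenced 3, while without control 1 there were 267 lower and without SET-2 silenced 1 there were 289 lower. Leaving out SET-2 control 1, 2 or 3 gave 17 to 29 higher and 20 to 33 lower, SET-2 silenced 2 or 3 gave 45 to 54 and 67 to 69, and both February 2018 libraries gave 1013 and 1220.

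Genes that changed in SET-2 mostly had the same sign in DAMI. Of the genes that rose in SET-2, 268 of the 290 tested in DAMI were higher there (92.4%, median log2 fold change 0.71), and of those that fell 225 of 249 were lower (90.4%, median -0.62); of the genes not called in SET-2 50.5% were higher. Tested in DAMI against all other genes, a test chosen after seeing the data, the SET-2 sets had p = 0.0106 and 0.0143 by camera with an estimated correlation. At an unadjusted p under 0.05 in DAMI, 125 of the higher and 108 of the lower genes passed in the same direction, where 16.4 and 14.4 would be expected of independent lists. Across 18259 genes the fold changes of the lines correlated at Pearson r = 0.51 and Spearman rho = 0.50; genes are not independent replicates. No gene passed edgeR's test in both lines (0 higher and 0 lower, since DAMI had none), against 105 and 109 with DESeq2. The correlation was 0.09 with no filter on low counts and with DESeq2, which was run without that filter. With the label date as a block in DAMI the p values of the SET-2 sets by camera with an estimated correlation were 0.0759 and 0.168. Without control 1 of DAMI that of the lower set was 0.0557.

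**Figure D4:**
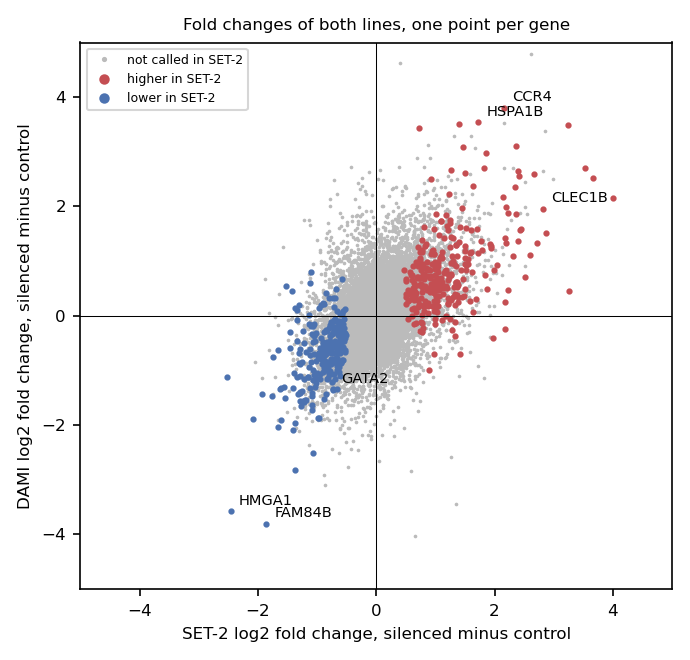
Log2 fold change, silenced minus control, in DAMI against SET-2, with 1 point for each of the 18259 genes tested in both lines. Genes higher (red) or lower (blue) in SET-2 mostly share their sign in DAMI: 268 of 290 and 225 of 249.

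The average response of both lines, chosen after seeing the data, passed for 629 genes higher and 604 lower of 23264, 326 of them SET-2 calls. The naming rule here asked for all silenced libraries on one side of all controls in both lines. Among genes that met it, SLCO2B1 (log2 fold change 3.06, SE 0.52, adjusted p = 0.00919), CCR4, DLGAP3, HSPA1B, TMEM40, HSPA1A, PRSS23 and CLEC1B (2.36, SE 0.35, adjusted p = 0.00456) had the largest rises. The size of those of HSPA1B (2.62) and HSPA1A (2.45) rests in part on DAMI silenced 2. Without it they were 1.48 and 1.28 and still passed (adjusted p = 0.00385 for each). Both also passed without both February 2018 libraries (0.00333 and 0.00360). Without any 1 SET-2 library but silenced 1 they did not pass (adjusted p 0.0563 to 0.0856), nor did HSPA1A without DAMI control 1 or 2 (0.0503 and 0.0569). HSPA1B and HSPA1A also did not pass with library numbers as a block (0.134 and 0.144) or with no filter on low counts (0.117 and 0.140), nor HSPA1A with limma-voom (0.0579). By the same rule, after HMGA1 (-3.04, SE 0.31, adjusted p = 0.00137), FAM84B (-2.85, SE 0.29), SMARCA1, GPR153, BBS2, SYAP1, PKLR, the red cell pyruvate kinase, and LZTFL1, which binds the BBSome, had the largest falls. Of the fixed genes, GATA2 (-1.06, SE 0.15, adjusted p = 0.00447) and MYC (-1.02, SE 0.21, adjusted p = 0.0197) fell and CDKN1A rose (1.07, SE 0.27, adjusted p = 0.0383). MYC and CDKN1A did not meet the rule. In SET-2 silenced 1 they stood at 580 and 29.6 CPM, within the control ranges of 575 to 652 and 24.5 to 34.4 CPM. Megakaryocyte genes had a median of 0.69, with 6 higher over all genes and 12 higher and 1 lower of 34 adjusted over the list alone, TUBB1, the platelet beta-tubulin, among them (camera adjusted p = 8.16e-08; 0.563 with an estimated correlation). Mitochondrial transcripts (median 0.52), histone genes (0.53), non-blood markers (0.65) and heat shock genes (0.27), signs of RNA quality, RNA selection, other cells and handling, passed camera as higher in the same average, with adjusted p 0.563 for the first 3 and 0.630 for heat shock genes with an estimated correlation. The counts were 262 and 279 with library numbers as a block and lay between 101 and 359 higher and 101 and 300 lower without DAMI silenced 1 or 3 or any SET-2 library but silenced 1. Without DAMI silenced 2 they were 1210 and 1526, and without SET-2 silenced 1 there were 969 lower; of the 43 genes the naming rule gave for the average, 17 to 42 stayed past the threshold without 1 library.

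The response did not differ detectably between the lines for any gene. The test of the difference, DAMI minus SET-2, called 0 of 23264 genes with edgeR (lowest adjusted p = 0.923; 1042 at an unadjusted p under 0.05 against 1163.2 expected), 0 with limma-voom and 14 with DESeq2. The lowest p values were those of DNASE2, SH3PXD2A, GFI1, a repressor of myeloid genes, UBE2C, RAP1GAP, WWC1, SFRP5 and ELK3. DNASE2 had a difference of -2.51 (SE 0.41), with log2 fold changes of -2.19 in DAMI and 0.30 in SET-2, and GFI1 of -1.51 (SE 0.29), with -1.78 and -0.29. The count was 6 without DAMI control 1 and 65 without both February 2018 libraries. In simulated libraries this test found 34% of genes that differed 4-fold, so smaller differences were mostly beyond its reach.

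**Figure D5:**
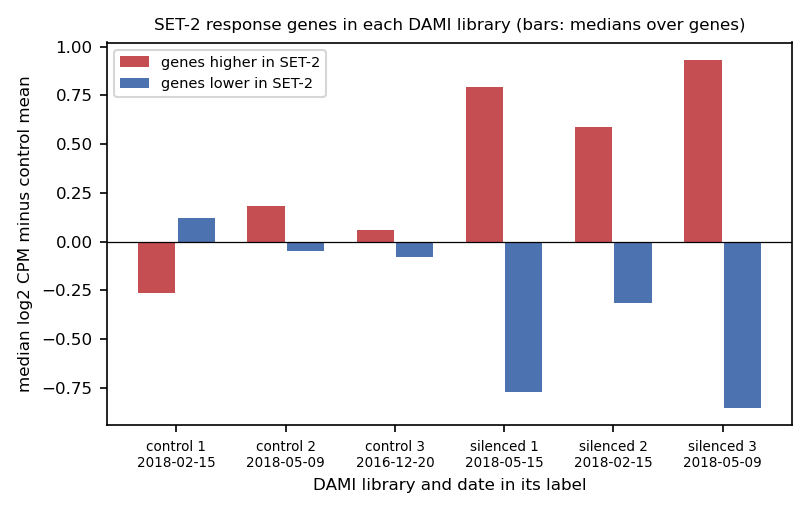
Median log2 CPM minus the DAMI control mean, per DAMI library, of the genes that rose (red) and fell (blue) in SET-2, with the date in each label. Silenced library 2, of February 2018, shows the smallest separation of the 3 silenced libraries, and control 1, of the same day, lies on the opposite side of 0.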

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

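The test of gene lists on the difference between lines, its alternatives, the removal of both February 2018 DAMI libraries and the splits kept to the pairs were chosen after the result was seen, while the test of single genes was planned. Between the lines, 9 gene lists differed in their response by camera on the difference of the log2 fold changes, DAMI minus SET-2, while edgeR called no single gene (1042 at an unadjusted p under 0.05), DESeq2 14, and edgeR 1 with no filter on low counts, 6 without DAMI control 1 and 65 without both February 2018 libraries. Genes of the amino acid and unfolded protein stress response had a median difference of -0.80 (adjusted p = 5.58e-11), with medians of -0.70 in DAMI and 0.18 in SET-2. Replication-dependent histone genes had a median difference of 0.63 (adjusted p = 1.20e-07), with 0.93 in DAMI and 0.26 in SET-2. The difference was 0.44 for cholesterol genes (adjusted p = 0.000169) and 0.57 for hypoxia and glycolysis genes (adjusted p = 0.00964). It was -0.14 for MYC targets, -0.56 for mast cell and basophil genes, 0.47 for other high mobility group genes, -0.37 for mitochondrial transcripts and 0.35 for heat shock and immediate early genes, each with an adjusted p of 0.0491. With the correlation estimated, each of the 9 had an adjusted p of 0.894 with an estimated correlation.

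In other splits of the 12 libraries within the lines, 79 of 100 gave as many differing lists as the real 9, with 19 as the highest of the others, so chance is not excluded for the number of lists, nor among the 32 splits that part as many pairs of label day and number as the real one, where 25 gave as many. For single genes the real count of 0 is reached by each of the 100 splits whatever the data, so that count says nothing about chance, and the highest other gave 432. That highest split joined the 3 DAMI libraries of May 2018 and reversed the real SET-2 groups, so its count holds the SET-2 response itself. The stress and histone lists kept their camera call without each library in turn. Cholesterol genes lost it without DAMI control 3 or silenced 2 (adjusted p = 0.110 and 0.281), and hypoxia genes without DAMI control 3 or silenced 2 or SET-2 control 1 or silenced 1 (0.320, 0.338, 0.0787 and 0.595). Of the 5 lists at 0.0491, at least 1 lost its call without each of the 12 libraries, with adjusted p from 0.0503 to 0.760. The number of lists was 5, 3 and 5 without DAMI control 2, control 3 and silenced 2, and 4 and 5 without SET-2 control 1 and silenced 2. Without both February 2018 libraries 2 of the 9, the stress and mast cell lists, stayed past camera. There the difference was 0.08 for histones (adjusted p = 0.240), 0.15 for cholesterol (0.407), -0.22 for mitochondrial (0.432) and -0.06 for hypoxia genes (0.848), and MYC targets, other high mobility group and heat shock genes had adjusted p 0.609, 0.617 and 0.912.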

How the results depend on the processing

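The average of both lines, the DAMI result of all 12 libraries, SET-2 genes within DAMI, the gene lists that differ between lines, the month as a block and the removal of both February 2018 libraries were chosen after the result was seen. The cause was not tested unless said. HMGA1 was lower under every setting run. In SET-2 its log2 fold change was -2.46 (adjusted p = 0.0770) in the fit of all 12 libraries and lay between -3.13 and -2.20 with 1 library left out. In DAMI it passed with DESeq2 (-3.61), with no filter on low counts (-3.69), with all 12 libraries (-3.61) and with the date as a block (-4.01), and lay between -3.96 and -3.29 with 1 left out.

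SET-2 counts, higher and lower, were 1148 and 897 with DESeq2, 195 and 214 with limma-voom, 1442 and 1075 with no filter, 0 and 0 with all 12 libraries (edgeR; 2208 at an unadjusted p under 0.05), 1299 and 1176 with library numbers as a block, and from 0 to 2518 and from 0 to 2479 with 1 library left out. DAMI counts were 212 and 209 with DESeq2, 67 and 108 with no filter, 138 and 158 with all 12 libraries, 4 and 1 with the date as a block, and 0 and 0 with edgeR under the title numbers or the month as a block (3520 at an unadjusted p under 0.05 for the month) and without any 1 library. Genes in both lines were 105 and 109 with DESeq2, 45 and 83 with no filter and 1 and 1 with the date block. The correlation was 0.0900 with DESeq2, which was run without the low-count filter, 0.0937 with no filter in edgeR and 0.617 with the stricter filter. It was 0.332 with all 12 libraries, 0.416 without the February 2018 libraries and 0.390 to 0.523 with 1 left out. SET-2 higher genes in DAMI kept 94.5% (estimated-correlation camera, no longer past the threshold) with the date block and 86.6% (likewise) without February 2018, and 87.0% to 94.6% with 1 left out. SET-2 lower genes kept 91.6% with title numbers as a block and 88.4% with the date block (both likewise), and 85.7% to 95.7% with 1 left out. Differing lists were 3 to 13 with 1 left out and 0 with an estimated correlation, and differing genes were 14 with DESeq2, 1 with no filter, 65 without February 2018 and 0 to 6 with 1 left out.

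The average called 1330 and 1163 with DESeq2, 262 and 279 with the block, 1610 and 1847 without February 2018, and 101 to 1210 and 101 to 1526 with 1 left out. The 12-library DAMI result gave 1013 and 1220 without February 2018, and 9 to 660 and 4 to 888 with 1 left out. No list passed with an estimated correlation or fry in either line, and 7 SET-2 lists passed with all 12 libraries.

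Medians that changed sign or test direction, for lists past camera or past it there, were, without February 2018, DAMI MYC targets -0.0280, hypoxia 0.0278 and ribosomal -0.0174, and, for the difference, G2/M -0.173, MYC targets 0.0156, ribosomal -0.169, hypoxia -0.0552, other high mobility group genes -0.00805 and heat shock -0.0652. Without DAMI silenced 2 they were MYC targets 0.0205, hypoxia -0.280 and ribosomal -0.121, and, for the difference, G2/M -0.212, MYC targets 0.0511, hypoxia -0.127, ribosomal -0.218 and heat shock -0.142. Without SET-2 silenced 1 they were SET-2 hypoxia 0.177 and, for the difference, MYC targets 0.154. With 1 library left out the medians lay between -0.350 and 0.0205 for DAMI MYC targets, -0.280 and 0.830 for DAMI hypoxia, -0.121 and 0.421 for DAMI ribosomal and -0.226 and 0.177 for SET-2 hypoxia. For the difference they lay between -0.212 and 0.242 for G2/M, -0.300 and 0.154 for MYC targets, -0.127 and 0.728 for hypoxia, -0.218 and 0.291 for ribosomal and -0.142 and 0.808 for heat shock. Of the other values for lists, 37 in DAMI, 15 in SET-2 and 18 for the difference gained a call, and 43, 43 and 59 lost it. Among the gains, DNA replication genes were lower in DAMI with the date block (-0.271, camera adjusted p = 4.69e-05). In SET-2 without silenced 1, DNA replication genes (-0.242, 5.53e-05) and MYC targets (-0.236, 5.47e-06) were lower. The remaining 305 in DAMI, 263 in SET-2 and 351 for the difference stayed on their side of the threshold. In 20, 22 and 36 of these the median had the other sign, in lists not past camera except for 6 in SET-2, all of the interferon list, whose median is near 0. Fewer libraries mean fewer degrees of freedom, and the spread between libraries, not depth, limits most genes.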

Other observations

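The tests chosen after the result was seen in this part are those on the average of both lines, on the 12-library DAMI result, on SET-2 genes within DAMI, on the amount of HMGA1, on SET-2 RNA, on a mislabelled library, on the splits kept to the pairs, and on genes called in DAMI for SET-2 library 1. In the average of both lines, 7 of 40 interferon response genes were higher, BST2 (log2 fold change 1.21, adjusted p = 0.0106), IFI6 (0.84, adjusted p = 0.0131) and RSAD2 among them, and DTX3L was lower; 11 higher and 4 lower passed adjusted over the list alone (camera adjusted p = 0.0282; 0.630 with an estimated correlation). Among p53 targets FAS, a death receptor (0.98, adjusted p = 0.0128), CDKN1A and BTG2, a growth inhibitor, rose and XPC, a DNA repair gene, fell, with 5 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.947). Among inflammatory genes CCL2, a monocyte attractant (3.42, adjusted p = 0.0269), and PLAUR rose and RELB fell, with 6 higher and 1 lower of 30 adjusted over the list alone (camera adjusted p = 0.0390, and 0.630 with an estimated correlation). CCL2 had too few counts to be tested in either line's own fit, where 29 members of this list were tested, so its rise is uncertain. Among genes of the amino acid and unfolded protein stress response PSPH, an enzyme of serine synthesis (-1.25, adjusted p = 0.0181), and the tRNA synthetases CARS and GARS fell and HSP90B1, a chaperone, rose, with 3 higher and 4 lower of 34 adjusted over the list alone (camera adjusted p = 0.0210; 0.821 with an estimated correlation). Of the 43 genes named for the average, 17 to 42 stayed past the threshold without 1 library, fewest without SET-2 silenced 2.

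Among the 10 splits of the 6 SET-2 libraries, the real one called 587 genes and the highest other 0, the 4 that part as many pairs included (1 of 10 as large); for gene lists 5 of 10 were as large, with 11 and 14. In DAMI the real count of 0 genes (edgeR; 2280 at an unadjusted p under 0.05, 421 calls with DESeq2) is reached by 10 of 10 whatever the data, which says nothing about chance, and the highest other was 4. There 7 of 10 were as large for lists, 11 and 15, and 2 of 10 for the 12-library DAMI result, 296 and 487. The 4 and the 487 come from the split that joins the 3 May 2018 libraries, and the label date as a block gave 4 higher and 1 lower. These splits are too few for a share under 0.05, as are the 20 for the SET-2 genes within DAMI, where the median of the higher minus that of the lower genes was 1.33 and the highest other 0.975 (1 of 20). Among 100 splits of both lines, 1 was as large for the correlation of fold changes (0.514, highest other 0.456) and 1 for the average response (1233 genes, highest other 186). For the correlation, which was planned, a share under 0.05 argues against chance. The average was chosen after the data were seen. Its share makes no allowance for that choice, so it does not exclude chance. Both shares take the libraries of a line as interchangeable, which the labels do not establish. These 100 ignore the pairs; all 32 splits that part as many pairs as the real one gave 1 as large for each, with 0.456 and 1 as the highest others. The mirror image of the split that called 432 genes for the difference was not drawn, and would call those 432 for the average. For mitochondrial transcripts 3 of 100 were as large (0.518, highest other 0.580), and 1 of the 32 (highest other 0.496). This list was taken up from the 23 after it had moved in both lines. The shares make no allowance for that choice, so they do not exclude chance for it.

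The megakaryocyte list passed camera as higher after silencing in both lines, with adjusted p = 0.671 in SET-2 and 0.650 in DAMI with an estimated correlation and, in DAMI, 0 of 32 members past edgeR's test over all genes or adjusted over the list alone. Scaling between libraries as the source is argued against: under RLE or library-total scaling the lowest median over both lines was still 0.510. Among 10000 random lists matched on expression the real median lay at percentile 100 in both lines, against a general rise of genes at that level. Of the splits, 4 of 100 gave as large an average median (0.692, highest other 0.733), and 1 of the 32 kept to the pairs (highest other 0.629). The list was taken up from the 23 after it had moved in both lines. The shares make no allowance for that choice, so they do not exclude chance. The loss with an estimated correlation leaves correlated genes open. The labels used here do not name the hairpin, so effects of it beyond HMGA1 cannot be told apart from those of silencing. In the same libraries non-blood markers (medians 0.46 in SET-2 and 0.76 in DAMI), mitochondrial transcripts (0.56 and 0.45) and heat shock genes (0.26 and 0.56) passed camera as higher, each with adjusted p = 0.671 in SET-2 and 0.650 in DAMI with an estimated correlation, and in DAMI the mitochondrial call ended with the date block (0.147) or without silenced 1 (0.169) and the heat shock call without silenced 2 (0.337) or control 2 (0.0932), so other cells, RNA quality and handling stay open beside an effect of silencing, none of them tested for this list.

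The genes that changed in SET-2 moved less in DAMI silenced 2 than in silenced 1 and 3: the median of the higher minus that of the lower genes was 0.901 there against 1.57 and 1.78. The amount of HMGA1 left is argued against by silenced 2, which kept the least, 3.97%. RNA of SET-2 cells in silenced 1 and 3 is argued against by genes near 0 in the other DAMI libraries, which reached at most 0.447% of their SET-2 level over 19 genes. Against same-day controls the gap between silenced 3 and 2 was 0.102 in place of 0.882, 11.6% of it, so the library date is a candidate explanation. No biological explanation other than the amount of HMGA1 was tested.

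In SET-2 silenced 1 the genes called without it moved less than in silenced 2 and 3, with a median share of the change of 0.290 (interquartile range -0.0102 to 0.608) over 4911 genes, or 0.369 (0.0792 to 0.708) against the control of the same number. Cells without silencing in that library would bring every gene to the share of HMGA1, 0.772. Because genes chosen on libraries 2 and 3 lower the share, the median change was also measured on 282 genes called for DAMI in the fit of all 12 libraries, whose spread is shared with SET-2: it was 26.8% in silenced 1 (25.9% to 27.5% against each control), where the share of HMGA1 would give 39.3%. It was 52.8% and 48.9% in silenced 2 and 3 and -0.170% to 0.545% for each control against the other controls, so the shortfall exceeds the gaps between these libraries and argues against cells without silencing as the whole source. A mislabelled control library is argued against by HMGA1 at 110 CPM, against 328 CPM in the lowest control, while a weaker response to partial silencing was not tested and stays open.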
